A study of Mus musculus with 2 samples.

How the data were processed

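Left lower lung lobes of male ICR mice aged 6 to 8 weeks were digested with collagenases, Dispase and trypsin, per the labels' protocols, and profiled with 10x Genomics 3' version 3 chemistry on an Illumina NovaSeq. There were 2 libraries, 1 of LPS mice and 1 of mice given LPS and miconazole, and each pooled the tissue of all mice of its group. The number of mice, the LPS dose, the timing and a map from cells to mice were not given in the sources used here. The age, the miconazole doses of 0.2 and 1.0 mg/kg and the pooling are per the labels.

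The deposited matrices held raw UMI counts per gene and cell barcode, per the file headers from Cell Ranger 7.0.0. Per the submitters' processing notes, bcl2fastq 2.20 and the mm10 build were used. Whether intronic reads were counted, and any filter beyond cell calling, were not given in the sources used here. No barcode in either deposited matrix had fewer than 500 UMIs. The LPS library held 12577 barcodes and 90597705 UMIs (median 5701 UMIs and 1369 genes per barcode), and the LPS_MCZ library 8500 barcodes and 68467793 UMIs (median 6102 UMIs and 1506 genes). Of 32285 genes listed, 23513 and 23038 had UMIs. The neutrophil genes S100a8 and S100a9 took 9.98% and 9.51% of UMIs, and Gm42418, a gene overlapping ribosomal RNA, 0.506% and 1.14%.

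Cells with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs numbered 12076 and 8314, and 12075 and 8314 were kept after 1 doublet call was removed. The gene limit removed 481 and 158 barcodes and the mitochondrial limit 34 and 47, some barcodes failing both. The median mitochondrial percentage of kept cells was 0.288 and 0.282. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked 1 LPS cell and 0 LPS_MCZ cells against expected rates of 9.66% and 6.65% (0.8% per 1000 cells), so the caller did not work here. An alternative that removed the highest scores at the expected rates was added. Counts were scaled to 10000 per cell and log transformed. The clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9), with both libraries together and no batch correction. It gave 25 clusters.

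Clusters were named from fixed marker sets of 25 classes. A class needed at least 3 markers at a log2 ratio of at least 1 over the 25th percentile of clusters, with a pseudocount of 20 CPM. The 10 leading genes could bar a name only for the innate lymphoid cell 2 class, which left cluster 24 unnamed. A named cluster was called by its number where its leading genes held more markers of another class than of its own. The naming gave 13 named classes and 3 unnamed clusters. Clusters with a median of under 0.3333 of the library's median UMIs were left unnamed. The naming baselines, this UMI limit and the rule that left cluster 24 unnamed were set after the clusters and a first look at macrophage ratios had been seen; the macrophage class was clusters 9 and 20 under every baseline. The unnamed clusters were cluster 7, nearest to alveolar macrophages (293 LPS cells, 2.43%, and 163 LPS_MCZ cells, 1.96%), cluster 16, nearest to classical monocytes (498, 4.12%, and 230, 2.77%), and cluster 24, led by Calca, Il17a and Il22 (52, 0.431%, and 27, 0.325%). Cluster 15 met the nonclassical monocyte markers, but its leading genes held 0 of them and 1 vascular endothelial marker, so it is called by its number. Cluster 0 held 0 neutrophil markers among its leading genes and 0 of another class, and kept the neutrophil name. The neutrophil class combined 8 clusters.

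UMIs were summed over the cells of each class and library and divided by the class total to give CPM, counts per 1e6. The macrophage sums were 7434571 and 6259363 UMIs. The log2 ratio of LPS_MCZ over LPS used a pseudocount of 1 CPM. Intervals are exact Poisson or Clopper-Pearson intervals at 95%, and cover counting alone, not variation between mice. Log2 intervals are of the ratio without the pseudocount, so for genes with 1 to 3 UMIs in a library the counts and interval are printed and no estimate. A count of 0 allows up to 3. Across 9727 genes with at least 50 UMIs in macrophages the log2 ratios had a median of 0.02 and a standard deviation of 0.44. The median over neutrophil genes was 0.12.

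The 23 gene lists (396 genes) were written before the data were examined, as were the main settings and the first alternatives. They cover M1 and M2 markers, cytokines and chemokines, NF-kB targets, interferon response, inflammasome, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid uptake and storage, cholesterol efflux and LXR targets, glycolysis, oxidative phosphorylation, MHC class II, lysosome, efferocytosis, dissociation response and proliferation, which were meant for macrophages (18 lists). The other lists were neutrophil activation, neutrophil granule and recruitment, endothelial activation, surfactant and epithelial acute phase genes. List members needed at least 20 UMIs over both libraries. Members beyond 0.5 either way were counted, the median was given an interval from 1000 Poisson resamples, and its percentile was taken among 10000 random lists drawn from the 200 genes nearest in expression to each member.

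Named genes were chosen by rule: the 12 highest and 12 lowest macrophage genes, the 4 highest and 4 lowest of other classes with at least 100 cells per library, the 4 list members with the largest ratios, and a fixed set of 20 polarization and lipid genes. Of the genes these rules chose, 3 are not reported here on their own and were not replaced, but they stayed in the gene lists. A gene needed at least 50 UMIs and 50 CPM in the higher library. A gene was called open to free RNA, and not ranked by size, where its CPM in the library with the higher value was under 0.1 of its CPM in another class. How this rule was applied was settled after the gene ranking had been seen. Members of the cholesterol list in neutrophil-like and classical monocyte-like cells, members of the endothelial lysosome and B cell proliferation lists, and resident markers were named after their values were seen. Gm42418 and BC018473 were left out of the ranking after their values were seen and are given in the closing section. Coordinates came from the GENCODE vM21 annotation, matched by Ensembl identifier (177 of 177 named genes matched, 176 with the same name).

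With 1 library per group no test between groups was made and no genes were called changed. The procedure was tested on simulated data made from the macrophage class (6570 genes): intervals held the simulated ratio for 95.6% of genes, mean estimates for ratios of 0.5, 1.0, −0.5 and −1.0 were 0.49, 0.96, −0.50 and −0.98, and a list raised by 0.5 reached percentile 100.0 while an unchanged list was at 57.6. The simulated counts had Poisson error only. This checked the computation, and not variation between mice or cells, doublets or free RNA.

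The alternatives were a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial), a filter on 200 genes only, doublet calls kept, resolution 0.5 and 2.0, libraries clustered separately, TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial and ribosomal protein genes, the mean over cells, thinning to 2000 UMIs, a pseudocount of 10 CPM, a minimum of 100 UMIs, and free RNA subtracted with neutrophil, B cell and alveolar type 2 markers. Seen shares of cells were also taken at 1000 UMIs and without thinning. The removal of the highest doublet scores and the naming of low-UMI clusters were added after results were seen. Computation used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.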

Results

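The series gave droplet single-cell RNA counts from the left lower lung lobe of male ICR mice, an outbred stock, with lung inflammation induced by lipopolysaccharide (LPS). There was 1 library of LPS mice and 1 library of mice given LPS and miconazole (MCZ), an azole antifungal injected into the peritoneum. Each library pooled the lungs of all mice of its group. The miconazole dose was 0.2 mg/kg in the sample label and 1.0 mg/kg in the protocol text. After filtering, 12075 cells of the LPS library and 8314 cells of the LPS_MCZ library were compared, at a median of 5809 and 6180.0 UMIs (transcript tags) per cell. With 1 library per group no test between groups was possible, and treatment could not be told apart from library. Ratios below are log2 of LPS_MCZ over LPS, on summed counts scaled to a common total (CPM), and brackets hold 95% intervals that cover counting error only.

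Neutrophil-like cells were the largest class in both lungs, and made up a larger share with miconazole. They were 63.1% [62.2, 63.9] of LPS cells (7615) and 69.4% [68.3, 70.3] of LPS_MCZ cells (5766). Lymphocytes made up smaller shares: T cell-like cells 6.98% [6.53, 7.45] and 3.48% [3.09, 3.89], B cell-like cells 2.36% [2.10, 2.65] and 1.21% [0.991, 1.47], NK cell-like cells 3.05% [2.75, 3.37] and 1.85% [1.57, 2.17]. Classical monocyte-like cells were 6.94% [6.49, 7.41] and 7.75% [7.18, 8.34], vascular endothelial-like cells 1.97% [1.73, 2.23] and 2.53% [2.2, 2.89]. Erythroid-like cells were 1.24% and 1.46%, conventional dendritic-like cells 1.02% and 0.914%, fibroblast-like cells 0.812% and 1.13%, alveolar type 2-like cells 0.389% and 0.433%, and platelet-like cells 0.489% and 0.325%. Cluster 15, which carried nonclassical monocyte markers and was led by Ccl5, Ms4a6c and Hspa1a, held 1.86% [1.63, 2.12] and 1.34% [1.10, 1.61]. Shares of 1 library depend on digestion and loading, and a larger share of 1 class lowers the shares left to the others. The order of the classical monocyte-like shares turned around when libraries were clustered separately and when low-UMI clusters were named.

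Alveolar macrophage-like cells, the lung's resident phagocytes, were 343 LPS cells (2.84% [2.55, 3.15]) and 265 LPS_MCZ cells (3.19% [2.82, 3.59]). Both clusters of the class had the lipase gene Lpl among their leading genes. Cluster 9, led by Slc7a2, Lpl and Ccl9, held 82.2% of the class in LPS and 35.5% in LPS_MCZ. Cluster 20, led by Plet1, Plcb1 and Mrc1, held 17.8% and 64.5%. The order of the class shares was not stable: it was 4.49% and 4.01% with a stricter cell filter, 5.25% and 5.15% at clustering resolution 0.5, and 5.27% and 5.15% with low-UMI clusters named.

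Interferon-response genes were the gene group with the lowest ratios in alveolar macrophage-like cells with miconazole. Of 23 measured genes of the list, 23 were below 0 and 20 were lower by more than 0.5, with a median of −1.01 [−1.11, −0.94], or 2.02-fold lower. Rsad2, the antiviral gene of viperin, was lower by 3.43-fold (−1.78 [−1.91, −1.67]). Ifit2 (−1.72), Oasl1 (−1.60), Usp18 (−1.57), Ifit1 (−1.51) and Ifit3 (−1.50) were also lower. The chemokine gene Ccl5, which interferon induces, was at 2541 CPM in LPS and 670.04 CPM in LPS_MCZ (−1.92 [−1.97, −1.87]). Rnf213 (−1.69) and Ifi202b (−1.48) were further interferon-inducible genes among the 12 lowest of the class. Within cluster 9 the list median was −0.53 [−0.64, −0.45], and within cluster 20 it was −0.07 [−0.19, 0.16]. With free RNA (RNA released from other cells into the droplets) subtracted the median was −1.78.

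Inflammatory chemokine genes were lower as well. The neutrophil-attracting chemokine gene Cxcl3 was the lowest of the genes ranked by size in the class, 5125 CPM in LPS and 1149.8 CPM in LPS_MCZ, 4.45-fold lower (−2.16 [−2.19, −2.12]). The scavenger-chemokine gene Cxcl16 (−1.57), Ccl3 (−1.28) and Ccl4 (−1.10) were lower, and Cxcl9 (−1.60) was open to free RNA. Of 21 cytokine and chemokine genes 9 were lower by more than 0.5 and 0 higher, median −0.25 [−0.34, −0.21], and the list was lower within both clusters (−0.55 and −0.49). Il1b was 1.42-fold lower (−0.51 [−0.54, −0.47]), whereas Tnf (0.08 [0.03, 0.14]) and Il6 (0.08 [−0.08, 0.25]) were close to equal. Inhba, the activin A subunit gene, was 3.50-fold lower (−1.81 [−1.89, −1.74]), and Lad1 was lower (−1.60). Tnf turned direction when cells were thinned to 2000 UMIs (−0.01).

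The NF-kB targets as a list were near equal, −0.09 [−0.14, −0.02], with 1 of 18 higher and 2 lower: Sod2 −0.78, Nfkb2 −0.75, Nfkbie −0.50 and Nfkbiz 0.67. The neutrophil activation list, applied to macrophages, was at −0.14 [−0.32, −0.12], with 0 of 15 higher and 4 lower. Inflammasome genes were at 0.15 [0.08, 0.24], with 0 of 11 beyond 0.5 either way (Txnip 0.48, Pycard 0.43 and open to free RNA, Casp1 −0.35, Nlrc4 −0.32). After thinning the inflammasome median was −0.10.

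The list median of classical (M1) polarization markers was below 0 in the class as a whole, and markers of alternative (M2) polarization were mixed. Neither list was evaluated within the macrophage clusters. Of 14 measured M1 genes 5 were lower and 0 higher by more than 0.5, median −0.21 [−0.35, −0.10], with Cd38 −1.82, Fpr2 −0.63 and Cd40 −1.19, the last open to free RNA. Nos2 had 38 UMIs in LPS and 20 in LPS_MCZ (−0.54 [−1.54, 0.14]), and Cd86 was equal within counting error (0.04 [−0.24, 0.31]), both open to free RNA. Of 14 measured M2 genes 4 were higher and 3 lower, median −0.06 [−0.25, 0.17]. Mrc1, the mannose receptor gene, was 1.69-fold higher (0.76 [0.71, 0.81]), Klf4 was higher (1.39), and Chil3 was higher (0.42 [0.40, 0.44]). However, Mrc1 was a leading gene of cluster 20, which held 17.8% of the class in LPS and 64.5% in LPS_MCZ. Ratios of these genes within the clusters were not taken. Arg1, the arginase gene, had 2 UMIs in LPS and 37 in LPS_MCZ (interval 2.5 to 7.56), and Retnla had 9 and 4. Both Arg1 and the lower Ccl17 (−1.74) were open to free RNA, and Ccl17 was near 0 with the highest doublet scores removed.

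Genes of fatty acid oxidation were higher with miconazole in alveolar macrophage-like cells. Of 21 genes 19 were above 0, 6 were higher by more than 0.5 and 0 lower, median 0.32 [0.25, 0.45]. The examples were the mitochondrial enzyme genes Hadh (1.12), Hadhb (0.66) and Acadm (0.64). Lipid uptake and storage genes had a median of 0.18 [0.11, 0.32], with 5 of 21 higher and 1 lower. The fatty acid translocase gene Cd36 was 1.73-fold higher (0.79 [0.72, 0.87]), the lipid droplet gene Cidec (1.35) and Lpin1 (1.09) were higher, and Acsl1 was lower (−0.99). Pparg, a regulator of alveolar macrophage lipid handling, was higher (0.52 [0.41, 0.63]), Fabp4 was at 0.27 [0.22, 0.33], and Plin2 was equal (−0.02 [−0.06, 0.02]). Within cluster 9 the oxidation median was 0.26 [0.14, 0.40], and within cluster 20 it was 0.06 [−0.09, 0.16].

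Fatty acid synthesis genes had a median of 0.28 [0.10, 0.41], with 3 of 12 higher and 1 lower. The desaturase genes Scd1 (43 and 179 UMIs, 2.13 [1.82, 2.82]) and Scd2 (1.50) were higher, as was Oxsm (0.66), while Me1 (35 and 11 UMIs, −1.05 [−2.55, −0.41]) was open to free RNA. Glycolysis genes were at 0.16 [0.08, 0.22], 3 of 16 higher and 0 lower, with Hk1 0.59, Pkm 0.57, Slc2a1 −0.33 and Slc16a3 0.60, the last open to free RNA. Oxidative phosphorylation genes were at 0.13 [0.09, 0.16], 33 of 39 above 0 and 0 beyond 0.5, with Ndufb10 at 0.42. After thinning the oxidative phosphorylation median was −0.003 and Ndufs7 (0.37), Sdhd (0.35) and Ndufa6 (0.33) were below 0.

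Cholesterol genes divided by function in the macrophage class taken as a whole. Export genes and targets of the sterol-sensing receptor LXR were higher, 5 of 14 by more than 0.5 and 1 lower, median 0.29 [0.20, 0.42]: Abcg1 0.62 [0.57, 0.67], Smpdl3a 0.72, Abca1 0.35 [0.24, 0.47], and Apoe 1.29, the last open to free RNA. Ch25h, an LPS- and interferon-induced cholesterol hydroxylase gene, was lower (−1.32). Synthesis genes and SREBP2 targets were lower, 18 of 23 below 0 with 1 lower by more than 0.5, median −0.22 [−0.29, −0.08]. Among them Idi1 was at −0.62, Hmgcs1 −0.48 [−0.70, −0.28], Stard4 −0.37, Cyp51, the mammalian form of the sterol demethylase that azoles inhibit in fungi, −0.30 [−0.59, −0.04] and Sqle −0.27 [−0.73, 0.13]. The synthesis median was 0.11 [−0.01, 0.24] within cluster 9 and −0.21 [−0.29, 0.17] within cluster 20. Both intervals spanned 0, so a lower value was not established inside either cluster. The LXR median was 0.25 [0.07, 0.29] within cluster 9 and 0.06 [−0.08, 0.16] within cluster 20.

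Genes of phagocytic clearance and of lysosomes were higher with miconazole in the macrophage class taken as a whole. Of 10 efferocytosis and resolution genes, 7 were higher and 1 lower by more than 0.5, median 0.60 [0.48, 0.66]: the lipid receptor gene Trem2 1.42, Spp1 0.78 and Tgfbr2 0.66. Timd4, a receptor gene of resident macrophages, had 32 UMIs in LPS and 1 in LPS_MCZ (interval −10.10 to −2.17) and was open to free RNA. Of 28 lysosomal genes 24 were above 0 and 5 were higher by more than 0.5, median 0.22 [0.18, 0.30], with Gpnmb 1.32, Ctsd 0.77, Cd63 0.61 and Ctsk 0.59. Markers of resident alveolar macrophages were higher for Cidec, Siglecf (1.17), Ear2 (1.00), Ear1 (0.96), Plet1 (0.57) and Krt79 (0.23), with Marco at −0.18. The lysosome list was at −0.0007 within cluster 20 and 0.20 within cluster 9. The efferocytosis list and the resident markers were not evaluated within the clusters.

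Early-response genes, which tissue digestion also induces, were higher in the macrophages: 9 of 18 higher and 2 lower, median 0.52 [0.47, 0.54]. Fosb was 4.32-fold higher (2.11 [2.02, 2.21]), with Egr1 1.19, Fos 0.99 and Btg2 0.85. The other genes with the highest ratios were the axon-guidance-related Nav2 (3.96-fold, 1.99 [1.87, 2.13]), the ether lipid monooxygenase gene Agmo (1.86), Adgrl3 (1.74), Krt19 (1.66), Cmss1 (1.66), Kcnip4 (1.63), Sh2d1b1 (1.60), Fam129a (1.59), Camk1d (1.59), Tns1 (1.59) and Tnfsf13 (1.56). Proliferation genes were higher for 7 of 19 and lower for 1, median 0.40 [0.23, 0.58], on few UMIs: Top2a 24 and 60 (open to free RNA), Cdk1 13 and 32, Cenpf 9 and 21, Stmn1 55 and 88. Nav2, Agmo, Adgrl3, Cmss1, Kcnip4 and Camk1d are long genes that overlap other annotated genes. Whether intronic reads were counted was not given in the sources used here. Gm42418, which overlaps ribosomal RNA, was also higher in these cells (1.66), with a ratio equal to that of Cmss1. With libraries clustered separately the Fosb ratio was higher still and the proliferation median was 2.62.

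Antigen presentation was not settled in the macrophages. Of 7 measured MHC class II genes 4 were lower and 2 higher, median −0.60 [−0.99, −0.03], with Cd74 (−1.11), H2-Ab1 (−1.01) and H2-DMb2 (8 and 24 UMIs, 1.22 [0.63, 3.20]) open to free RNA and H2-DMb1 at 1.05. The median was 0.61 with the stricter filter and 0.83 with the highest doublet scores removed, with Cd74 at 0.45 and 0.65. Lists of other cells' genes often held genes open to free RNA: neutrophil granule genes 0.48 [0.46, 0.63] with 9 of 13 open (0.32 to 3.11 over the alternatives), led by Padi4 (12 and 53 UMIs, 1.86 [1.47, 3.43]), surfactant genes 0.34 [0.19, 0.54] with 4 of 12 open, acute phase genes 0.14 [0.05, 0.38] with 9 of 13 open, and endothelial activation genes 0.15 [−0.01, 0.33] with 6 of 12 open. Padi4 itself was not open to free RNA by the rule used.

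**Figure D1:**
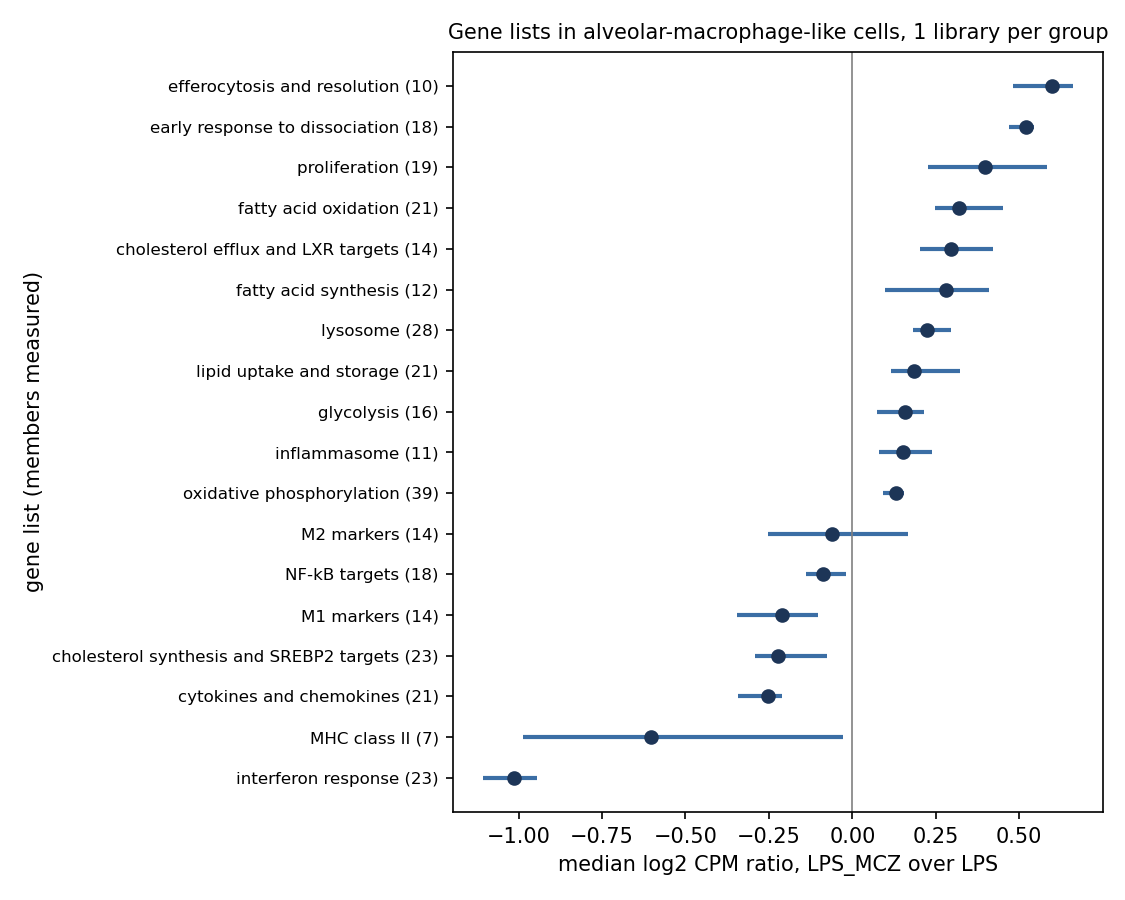
Median log2 CPM ratio (LPS_MCZ over LPS, horizontal axis) of each gene list (vertical axis) in alveolar macrophage-like cells. Points are list medians and bars are 95% counting intervals of the median from 1000 resamples, 1 library per group.

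Against 10000 random lists of genes of like expression, the list medians fell at the extremes for part of the 18 lists meant for macrophages. Percentiles of the lists meant for other cells are not given here. The interferon list was at percentile 0, MHC class II 0.01, cholesterol synthesis 0.11, cytokines 0.30, M1 markers 1.50, NF-kB targets 15.8 and M2 markers 17.1. On the high side were inflammasome 91.2, glycolysis 95.8, fatty acid synthesis 96.4, lipid uptake 98.1, oxidative phosphorylation 99, proliferation 99.6, LXR targets 99.7, lysosome 99.9, fatty acid oxidation 99.95, efferocytosis 99.97 and dissociation 100. These percentiles compare genes with genes and say nothing of variation between mice.

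The share of macrophages in which a gene was seen was compared with each cell thinned to 2000 UMIs (3 LPS cells left out, 0 LPS_MCZ cells). Median depth was 21888 and 22880.0 UMIs in the macrophages and 5954 and 7291 in T cell-like cells, set beside them as a class that should lack most of these genes. Mrc1 was seen in 72.1% [67.0, 76.8] of LPS and 89.4% [85.1, 92.9] of LPS_MCZ macrophages (T cell-like 0.267% and 0.370%). Cd36 was seen in 39.4% [34.2, 44.8] and 52.8% [46.6, 59.0] (T cell-like 0.267% and 1.48%), Fabp4 in 49.1% [43.7, 54.6] and 64.5% [58.4, 70.3] (1.33% and 2.22%). Pparg was seen in 22.6% [18.3, 27.5] and 33.6% [27.9, 39.6] (0.40% and 0.741%), Abcg1 in 69.7% [64.5, 74.5] and 79.2% [73.9, 84.0] (14.3% and 11.1%, against 3.15% and 3.96% of erythroid-like cells). For Il1b the shares were 89.7% [86.0, 92.7] and 78.9% [73.5, 83.6] (T cell-like 38.1% and 47.0%), for Tnf 51.2% [45.7, 56.6] and 56.2% [50.02, 62.3] (7.47% and 8.52%). In erythroid-like cells, of median depth 6406 and 6175 UMIs, Il1b was seen in 74.0% and 70.3% and Tnf in 22.0% and 25.7%, so for Il1b the background was close to the LPS_MCZ macrophage share. Arg1 was too sparse for thinning: with all UMIs it was seen in 2 of 343 LPS macrophages (0.583% [0.0707, 2.09]) and 9 of 265 LPS_MCZ macrophages (3.40% [1.56, 6.35]), and in 0.356% and 0.692% of T cell-like cells. Abca1 shares were 22.4% and 31.3% but 14.0% and 12.5% when thinned to 1000 UMIs. Pparg was then seen in 13.4% and 14.0%, so its difference did not hold at that depth either. Fabp4 was then seen in 37.0% [31.9, 42.4] and 45.7% [39.6, 51.9], with overlapping intervals. Without thinning Il1b was seen in 98.8% and 99.2%. Mrc1 and Fabp4 were among the leading genes of macrophage cluster 20, and shares were not taken within the macrophage clusters.

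Interferon-response list medians below 0 were not limited to the macrophage class, but how much free RNA added to them stays open. Of 12 classes 10 had list medians with intervals below 0: T cell-like −0.56 [−0.64, −0.43], B cell-like −0.70 [−0.76, −0.48], NK cell-like −0.50 [−0.64, −0.32], conventional dendritic-like −0.63 [−0.80, −0.56], endothelial-like −0.54 [−0.62, −0.44], fibroblast-like −0.45 [−0.59, −0.27], neutrophil-like −0.41 [−0.43, −0.39], classical monocyte-like −0.25 [−0.33, −0.20] and erythroid-like −0.88 [−1.07, −0.78], besides the macrophages. Cluster 15 (−0.06 [−0.15, 0.04]) and alveolar type 2-like cells (0.09 [−0.09, 0.31]) spanned 0. In T cell-like cells Cxcl10 (−1.46) and Ifit2 (−1.33) were among the lowest genes, and in cluster 15 Cxcl10 (−1.84). With free RNA subtracted the B cell-like median was 0.31 and the NK cell-like median −0.05. For erythroid-like cells, neutrophil markers put the free RNA share at 0.753 in LPS and 0.596 in LPS_MCZ. Only 9 of the 12 classes had at least 100 cells in each library, and the dendritic-like, fibroblast-like and alveolar type 2-like classes did not.

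Cholesterol synthesis genes were higher with miconazole in neutrophil-like and classical monocyte-like cells. In neutrophil-like cells 15 of 22 were higher and 0 lower by more than 0.5, median 0.60 [0.56, 0.71], and 6 were open to free RNA. The isomerase gene Idi1 was at 1.45, Cyp51 1.36, Msmo1 1.23, the sterol-sensing regulator gene Srebf2 1.23 [1.16, 1.35], Fdft1 1.12, Hmgcs1 1.04 [0.97, 1.18], and Acat2 −0.31. In classical monocyte-like cells 24 of 24 were above 0 and 5 higher by more than 0.5, median 0.39 [0.33, 0.45], with Sqle 0.59, Pmvk 0.59, Msmo1 0.56 and Hmgcs1 0.53. The median was 0.31 [0.05, 0.58] in endothelial-like cells and 1.26 [0.75, 1.82] in erythroid-like cells (6 genes). It spanned 0 in T cell-like (0.13), NK cell-like (0.01), B cell-like (−0.12), fibroblast-like (−0.08), alveolar type 2-like (0.09) and dendritic-like (−0.01) cells and cluster 15 (−0.01). In neutrophil-like cells TMM scaling put every ratio lower by 0.15, giving 0.46 for cholesterol and −0.56 for interferon genes, and the cholesterol median ran from 0.29 with a pseudocount of 10 CPM to 1.61 with free RNA subtracted. Members were sparse, with Idi1 at 5.54 and 16.8 CPM and Cyp51 at 3.16 and 9.65 CPM.

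**Figure D2:**
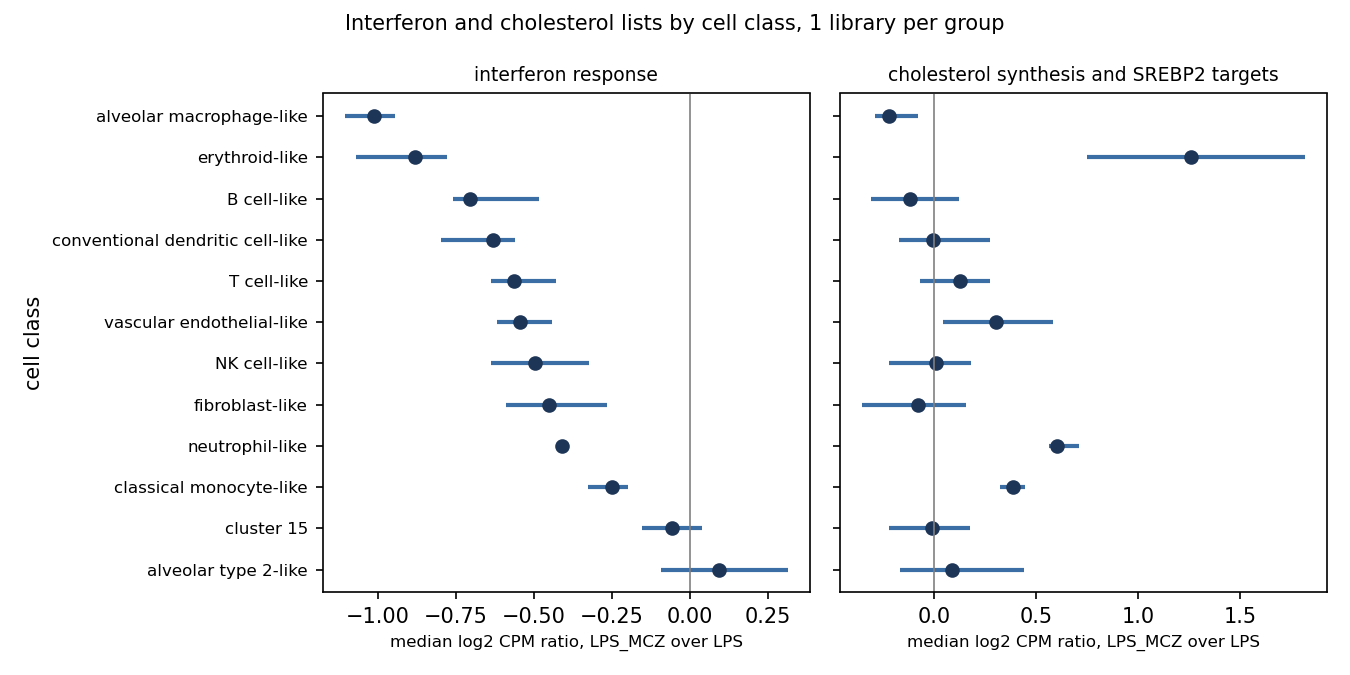
Median log2 CPM ratio (LPS_MCZ over LPS, horizontal axis) of the interferon and the cholesterol synthesis list in each cell class (vertical axis). Points are list medians and bars are 95% counting intervals of the median from 1000 resamples, 1 library per group.

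Neutrophil-like cells had lower inflammatory chemokine genes and higher Tnf with miconazole. The cytokine list was at −0.14 [−0.25, −0.06], with 7 of 21 lower and 1 higher, and ran from −0.53 to −0.07 over the alternatives. In the activation list, at −0.07 [−0.11, −0.04] with 4 of 15 lower and 2 higher, Ccl4 was at −0.97, the niacin receptor gene Hcar2 −0.94, Ccl3 −0.67 and Tnf 0.73 (416 and 690.3 CPM). Among granule and recruitment genes, 2 of 13 higher and 2 lower with a median of −0.14, the histone-citrullinating enzyme gene Padi4 (1.40) and the gelatinase gene Mmp9 (0.58) were higher. The secondary granule genes Camp (−1.01) and Ltf (−0.65) were lower. The lowest genes were Tspan13 (−1.65), Oser1 (−1.57), Schip1 (−1.45) and Stfa3 (−1.39), and the highest Bcl2l15 (2.22), Myo18a (1.77), the adhesion gene Ceacam1 (1.57) and Mbp (1.51). The 8 neutrophil-like clusters differed between libraries: clusters 0, 1, 2 and 3 were mostly LPS cells and clusters 4 and 5 mostly LPS_MCZ cells, so with 1 library each a cluster can stand for a library.

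In classical monocyte-like cells inflammatory genes were lower and Arg1 was higher. The cytokine list had 10 of 21 genes lower and 1 higher, median −0.42 [−0.48, −0.41], and 7 of 15 M1 genes were lower, median −0.42. Ccl4 was at −1.24 (2172 and 918 CPM), the ribonuclease gene Rnase2a −2.27, Serpinb2 −1.35 and the fungal-sensing lectin gene Clec4n −1.25. Arg1 was 2.47-fold higher (1.30, 696 and 1497 UMIs), with Crispld2 1.07, Hist1h2ap 0.95 and Spata7 0.89. Early-response genes were at −0.22, against the direction in macrophages. With libraries clustered separately Hist1h2ap was at −2.58.

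The extremes of lymphocyte-like classes included Cstdc5, Stfa2 and Ltf, which were leading genes of neutrophil-like clusters. Whether these came from free RNA or doublets was not tested. The free RNA share was estimated at 0.669 in LPS and 0.457 in LPS_MCZ for B cell-like cells. It was 0.254 and 0.216 for NK cell-like cells and 0.180 and 0.141 for T cell-like cells. For LPS B cell-like cells, neutrophil and alveolar type 2 markers put the share at 0.106 and 1.23. In T cell-like cells Trim30c (−2.33) and Cstdc5 (−1.33) were lowest beside the interferon genes. Irgc1 (3.47), the heme oxygenase gene Hmox1 (2.40), Fam129b (1.46) and Cmss1 (1.21) were highest, the last close to Gm42418 (1.17) in these cells. In NK cell-like cells Aass (−1.93), the heat shock genes Hspa1a (−1.65) and Hspa1b (−1.50) and Ltf (−1.52) were lowest, and the granzyme gene Gzmc (3.77), Lsamp (2.36), Mctp1 (2.07) and the growth factor gene Areg (1.79) highest. In B cell-like cells Stfa2 (−3.38), Egr1 (−2.16), Vmn2r96 (−2.02) and Fgl2 (−1.93) were lowest. The replication genes Gmnn (2.55), Mcm5 (2.33) and Top2a (2.05, 30 and 66 UMIs) were highest after Ly6k (1 and 57 UMIs, 4.28 to 12.14), and 9 of 10 proliferation genes were higher (median 1.31 [1.06, 1.72]). Gzmc in NK cell-like cells was −0.07, −1.98 and −0.14 at resolution 2.0, with separate clustering and with the highest doublet scores removed, where Ltf was 0.20 and Cstdc5 in T cell-like cells 1.52. Fgl2 was 0.21 with separate clustering, Cstdc5 0.27 at resolution 2.0 and Areg −0.01 after thinning.

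In vascular endothelial-like cells 3 genes of the endothelial activation list had low ratios on few UMIs. The E-selectin gene Sele had 84 UMIs in LPS and 8 in LPS_MCZ (−3.17 [−4.60, −2.30]), the chemokine-scavenging receptor gene Ackr1 63 and 12 (−2.24 [−3.37, −1.44]) and the vessel-destabilizing ligand gene Angpt2 36 and 6 (−2.33 [−4.07, −1.27]). The endothelial activation list had 5 of 17 genes lower and 3 higher, median −0.29 [−0.43, −0.15], and Ccl2 (2.68) was open to free RNA. Igfbp3 (−3.31), Ak8 (−3.15) and Alpk1 (−2.33) were the other lowest genes. Lsamp (3 and 160 UMIs, 4.21 to 8.08), Smoc1 (2 and 60 UMIs, 3.04 to 8.04), Slc16a10 (3.96) and the lysosomal phosphatase gene Acp5 (2.38) were highest. Lysosomal genes were higher for 16 of 26 (median 0.73 [0.48, 0.85]), with Atp6v0d2 (2 and 23 UMIs, 1.56 to 6.70), Ctss 1.54, Cd68 1.15 and Lipa 1.12, of which Atp6v0d2 and Cd68 were open to free RNA. The free RNA share of the class was estimated at 0.441 in LPS and 0.382 in LPS_MCZ. Smoc1 was −0.58 with the highest doublet scores removed.

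Alveolar type 2-like cells were few, 47 and 36, in a cluster that also had the club cell genes Scgb1a1 and Scgb3a2 among its leading genes, and their list directions did not hold across settings. Surfactant genes were higher for 4 of 15 and lower for 2, median 0.35 [0.20, 0.56], with Sftpa1 0.77, Sftpb 0.76, Lamp3 0.73 and Cebpa −0.88. Saa3, an acute phase gene, was 7.78-fold higher (2.96 [2.71, 3.23], 301 and 2353 CPM), and Cxcl1 was higher (1.36), while Krt8 (−0.98) was lower and Cxcl10 (−1.32) open to free RNA. The acute phase list was at 0.23 [0.05, 0.37], 3 of 14 higher and 3 lower. Averaged over cells the surfactant median was −0.66, the acute phase median −0.11 and Lamp3 −1.08, and thinned to 2000 UMIs Cebpa was 6.34.

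Erythroid-like cells and cluster 15 completed the compared classes. In erythroid-like cells Schip1 (−2.88), Tspan13 (−2.64), Cd69 (−2.41) and Chka (−2.13) were lowest, and Camkk2 (2.42), Ceacam1 (2.36), Ltf (2.04) and Cdc42se2 (1.84) highest. Of these Schip1, Tspan13 and Ceacam1 had the same direction in neutrophil-like cells, while Ltf went the other way. Neutrophil markers put the free RNA share of erythroid-like cells at 0.753 in LPS and 0.596 in LPS_MCZ, and B cell markers at 0.0277 and 0.0140. How far these ratios belong to erythroid-like cells therefore stays open. In cluster 15 Dennd5b (−2.05), Stk38l (−1.89) and Ccl4 (−1.48) were lowest beside Cxcl10, the cytokine list was at −0.56, and Cd24a (1.40), Rgs3 (1.36), Nxn (1.25) and Cks2 (1.21) were highest. In B cell-like cells the cytokine list was at −0.94, with 11 of 15 genes open to free RNA.

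The lead genes were all protein-coding genes, counted per gene from 3' tags and not per exon, at these places in mouse build mm10. Cxcl3 was on chromosome 5 from 90786103 to 90789600, Ccl5 on 11 from 83525778 to 83530518, Inhba on 13 from 16011851 to 16031621 and Rsad2 on 12 from 26442746 to 26456452. Fosb was on 7 from 19302696 to 19310051, Nav2 on 7 from 48908716 to 49610090, Cd36 on 5 from 17781690 to 17888801 and Il1b on 2 from 129364570 to 129371139. Mrc1 was on 2 from 14229392 to 14332057 and holds the microRNA gene Mir511 on its strand. Hmgcs1 was on 13 from 119690379 to 119708260, Scd1 on 19 from 44394455 to 44407879 and Arg1 on 10 from 24915221 to 24927484. Sele was on 1 from 164048234 to 164057677, Saa3 on 7 from 46711998 to 46715700 and Tnf on 17 from 35199381 to 35202007.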

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

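The tests that compare a list with its value over other barcodes (the equal-share free RNA tests) and the comparison of monocyte marker levels between classes were chosen only after related results had been seen; the other tests of this part were written before their own values, and all verdicts on free RNA were turned to undecided after the values were seen.

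Interferon-response genes were lower in alveolar macrophage-like cells of the LPS_MCZ library (median −1.01). Free RNA stays open: the class median minus the median over all barcodes (−0.33) was −0.68, but the profile of free RNA was assumed and erythroid-like cells were at −0.88 [−1.07, −0.78]. The subtraction of free RNA gave −1.78 and decides nothing either, since marker sets put the free RNA share of LPS macrophages anywhere from 0.0538 to 0.354. A different mix of the 2 macrophage clusters stays possible: the list was at −0.53 in cluster 9 and −0.070 in cluster 20, and the clusters were built from the same genes. A response of the mice to miconazole could be the reason, but with 1 library per group it cannot be told from any other difference between the pools.

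Fatty acid oxidation genes and resident markers were higher in the same cells. The median ratio of 7 classical monocyte markers in the class was −0.42, with Fn1 (0.52) and Ccr2 (0.34) above 0, and the test of fewer monocyte-derived cells was undecided. Monocytes that still carried their markers are argued against as a large part of the class by 3 markers: in LPS macrophages Ccr2 was at 6.99 CPM, Ly6c2 at 60.4 CPM and F13a1 at 28.9 CPM, against 384, 1457 and 1098 CPM in LPS classical monocyte-like cells, although Fn1 (290.3 against 623 CPM) and Ly6i (15.2 against 24.2 CPM) were closer. Monocyte-derived cells that had lost these markers could still differ in number, which stays open. Another mix of the 2 clusters was also undecided: the oxidation median was 0.059 in cluster 20 but 0.26 [0.14, 0.40] in cluster 9. The mix of the clusters as drawn does not account for the value inside cluster 9. The clusters were built from the same genes, so another mix of states inside cluster 9 stays open. Resident markers were not evaluated within the clusters.

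Cholesterol synthesis genes were higher in neutrophil-like cells. Scaling is argued against by the TMM median of 0.46. Another mix of the 8 clusters as drawn is argued against by the median of 0.58 with clusters weighted alike (0.52 to 1.11 within clusters). These clusters were built from the same counts and differed strongly in size between libraries, so another mix of states inside them stays open. Free RNA stays open: the class median lay 0.33 above that of all other barcodes (0.27), an assumed profile, and erythroid-like cells were at 1.26 [0.75, 1.82]. The subtraction of free RNA gave 1.61 and decides nothing, because marker sets put the LPS free RNA share from 0.0241 to 0.743. Azoles act on sterol synthesis, so a response to miconazole could raise these genes, but this was not tested and is confounded with library.

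The remaining differences between classes are given as values and were not tested. The macrophage cholesterol median minus that of neutrophil-like cells was −0.82, and minus that of classical monocyte-like cells −0.61. The dissociation response median of macrophages was 0.74 above that of classical monocyte-like cells, and the proliferation median 0.58 above. Gm42418 was at 5056 CPM over all LPS barcodes and 11381 CPM over all LPS_MCZ barcodes. BC018473 was at 914 CPM in LPS and 3.33 CPM in LPS_MCZ. The percentile bounds that picked these differences were chosen after values were seen.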

How the results depend on the processing

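The alternatives that removed the highest doublet scores and that named the low-UMI clusters, and the cholesterol and cytokine lists of neutrophil-like and classical monocyte-like cells, were chosen only after results had been seen. No paired analysis was possible because there was 1 library per group, and for the same reason no library could be left out in turn. For named genes 2708 values were recomputed over 197 results: 2217 stayed within the main interval, 471 moved and 20 reversed, in 15 genes. The cause was not tested for any of them. Over 15 alternatives the macrophage interferon median ran from −1.78 to −0.93, fatty acid oxidation from 0.23 to 0.45, efferocytosis from 0.52 to 0.70, macrophage cholesterol synthesis from −0.34 to −0.15 and M2 markers from −0.21 to 0.09. Neutrophil cholesterol synthesis ran from 0.29 to 1.61.

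All reversed values follow by setting, with the moved values of the main results: the AM and neutrophil shares and 7 AM lists (M1, M2, cytokines, interferon, cholesterol synthesis, fatty acid oxidation, LXR targets), AM standing for alveolar macrophage-like cells. Other moved values are not listed, apart from AM proliferation (2.62 with libraries clustered separately) and, with TMM scaling, neutrophil cholesterol synthesis (0.46) and interferon (−0.56). Stricter filter: AM share 4.49% LPS and 4.01% LPS_MCZ, neutrophil share 67.2% and 73.4%, AM MHC class II 0.61, H2-Ab1 0.28, Cd74 0.45. At least 200 genes only: neutrophil share 62.1% and 68.1%. Resolution 0.5: AM share 5.25% and 5.15%. Resolution 2.0: NK Gzmc −0.072, T cell Cstdc5 0.27. Libraries clustered separately: AM share 2.35% in LPS, AM cytokines −0.17, interferon −1.20, fatty acid oxidation 0.45, LXR targets 0.46, B cell Fgl2 0.21, NK Gzmc −1.98, classical monocyte Hist1h2ap −2.58. Low-UMI clusters named: AM share 5.27% and 5.15%. Highest doublet scores removed: AM MHC class II 0.83, H2-Ab1 0.48, Cd74 0.65, NK Ltf 0.20, NK Gzmc −0.14, T cell Cstdc5 1.52, endothelial Smoc1 −0.58. Free RNA subtracted: AM M1 −0.61, cytokines −0.42, interferon −1.78, acute phase −0.033, B cell interferon 0.31. Thinned to 2000 UMIs: AM interferon −1.11, inflammasome −0.10, oxidative phosphorylation −0.0030, Sdhd −0.15, Ndufs7 −0.11, Ndufa6 −0.019, Tnf −0.015, NK Areg −0.0062, alveolar type 2 Cebpa 6.34. Pseudocount 10 CPM: AM interferon −0.93, fatty acid oxidation 0.23. Mean over cells: AM cholesterol synthesis −0.34, alveolar type 2 surfactant −0.66, acute phase −0.11, Lamp3 −1.08. TMM scaling, totals without mitochondrial and ribosomal protein genes, at least 100 UMIs and doublet calls kept moved none of these main results, though TMM scaling moved 25 other values.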

Other observations

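The description of genes in this part was chosen only after their values had been seen, and no test was run on them. Dendritic cell-like cells, 123 and 76, had higher MHC class II genes in the LPS_MCZ library: 9 of 9 were above 0, with a median of 0.67. Fibroblast-like cells, 98 and 94, had a fatty acid oxidation median of 0.41. Early-response genes were lower in NK cell-like cells (−0.42), cluster 15 (−0.51) and alveolar type 2-like cells (−1.30, 16 of 18 lower), the reverse of alveolar macrophage-like cells.

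Over all barcodes 5 genes with at least 5 CPM in the higher library differed by at least 4 on the log2 scale, bounds chosen after values were seen. Those near absent in LPS_MCZ were BC018473 (82762 UMIs in LPS and 228 in LPS_MCZ), an antisense RNA gene on chromosome 11 from 116752167 to 116759373, its neighbour St6galnac1 (879 and 13) on chromosome 11 from 116765025 to 116775507, Gm10320 (769 and 17) on chromosome 13 from 98489348 to 98492001, and the peptide transporter gene Slc15a2 (505 and 13) on chromosome 16 from 36750177 to 36784962. Near absent in LPS was the granzyme gene Gzmc (61 and 921) on chromosome 14 from 56231441 to 56234656. BC018473 was lower in neutrophil-like cells (75051 and 203 UMIs) and T cell-like cells (1434 and 0 UMIs) alike. ICR mice are outbred, and which mice carried these transcripts cannot be told from pooled libraries.

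Gm42418 had a ratio of 1.66 in alveolar macrophage-like cells and between 0.96 and 1.19 in 8 other classes, 1.17 over all barcodes.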
